A study of Mus musculus with 4 samples.

How the data were processed

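Single-nucleus RNA was measured with the 10x Genomics 3′ v3 assay in hearts of C57BL/6 mice 6 months old. The labels describe total cardiac nuclei of 3 hearts pooled for each library, although the library protocol text also mentions CD45+ immune cells. There was 1 library for each of 4 genotypes: wild type (WT), a heterozygous Rbm20 mutation (Rbm20_het), a homozygous one (Rbm20_homo), and the homozygous mutation after gene editing correction (Rbm20_homo_corrected, called the corrected library here).

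The deposited matrices hold raw UMI counts per gene and nucleus barcode, per the file headers as whole numbers, with no normalization by the authors. The submitters' processing notes name Cell Ranger 6.1.1, Seurat 4 and the mouse build mm10 (GRCm38), whereas the matrix headers name Cell Ranger 4.0.0. The sources used here do not say whether intronic reads were counted or how barcodes were filtered. Each matrix has 32287 features, of which 32285 are mouse genes and 2 are added features called ABE_C and ABE_N, whose sequences the sources used here do not define. Of the genes, 26082 had at least 1 UMI. Gene positions came from the GENCODE vM21 annotation of GRCm38.

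Nuclei were kept with at least 300 genes and at most 5% mitochondrial UMIs, which removed 100 barcodes from WT, 114 from Rbm20_het, 99 from Rbm20_homo and 196 from the corrected library. Scrublet scores (scanpy 1.11.5) were computed per library and the highest-scoring nuclei were removed at 0.8% per 1000 barcodes. That took 713, 749, 1069 and 1813 nuclei in the same order of libraries, or 7.60%, 7.79%, 9.29% and 12.1%. Scrublet's own threshold marked 2, 985, 885 and 3163 nuclei and was not used, since in WT it found almost none. The 41139 nuclei left were clustered together with no batch integration, because library and genotype are the same thing here. Counts were scaled to 10000 per nucleus and logged, 2000 variable genes were chosen within libraries, and 30 principal components with 20 nearest neighbours and shared-neighbour weights fed Leiden clustering at resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9).

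The 29 clusters were named from fixed marker lists, with the suffix "like" because no annotation by the authors was used. A cluster took a name when at least 3 of that type's markers were enriched in it. The cluster-naming thresholds, and the use of a cycling class, were set after the data were seen. Of the clusters, 17 were named and 12 were not: 7 held markers of more than 1 type, 4 were small and 1 had low depth. Unnamed clusters held 10.8% of the WT nuclei, 11.4% of Rbm20_het, 9.84% of Rbm20_homo and 9.46% of the corrected library. Mixed clusters made up most of that, at 8.88%, 10.1%, 8.76% and 8.48% in the same order. Small clusters held 0.553%, 0.372%, 0.268% and 0.175%, and the cluster of low depth held 1.32%, 0.936%, 0.814% and 0.807%.

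UMIs were summed over the nuclei of a class in each library and expressed as CPM, the UMIs of a gene per 1e6 non-mitochondrial UMIs. Sums have exact Poisson intervals, ratios of sums exact conditional binomial intervals and shares of nuclei exact Clopper-Pearson intervals, all at 95%. Ratios of shares of nuclei have approximate 95% intervals on the log scale, with nuclei as units. A count of 0 is read as a limit of 3 counts per library. These intervals cover counting error only. With 1 library per genotype there is no replicate error, so no significance test between genotypes was run, no p-value is given and no changed genes were counted. Every difference below is a difference between libraries.

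Named genes followed a rule of size fixed in advance. In ventricular cardiomyocyte-like sums these were Rbm20, the 12 genes highest and 12 lowest in Rbm20_homo against WT, the 6 and 6 of the corrected library against each of WT and Rbm20_homo, and the 5 and 5 of Rbm20_het against WT. Genes were ranked by the interval bound nearest to 1, with at least 100 UMIs in the library with the higher CPM. In each other class the 6 and 6 of Rbm20_homo against WT were taken with at least 50 UMIs. Up to 4 members per gene list were named by the largest absolute log2 ratio of Rbm20_homo against WT and at least 100 UMIs over the 4 libraries. Left out were mitochondrial, haemoglobin and listed sex-linked genes, unnamed gene models, and genes whose CPM in the class was under 0.2 of that in another class of the same library in both libraries compared. Of the genes this rule named, 2 are not reported.

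For each of 20 gene lists, the median log2 ratio was taken over members with at least 50 UMIs in the 2 libraries together. Its percentile was read among 10000 random lists of the same size, matched on expression in 20 bins. For the measure of return to WT, the WT and Rbm20_homo nuclei were split at random into 2 parts of equal size. Genes were chosen in the first part where the interval bound passed 1.5-fold, and the median log2 ratio to WT, signed by the direction in the first part, was taken on the nuclei held out. A score per nucleus used the same genes, except Myh7b and genes above 1% of UMIs, after every nucleus was thinned to 1000 UMIs.

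The alternatives were all deposited barcodes (no filter and no doublet removal), a stricter filter (at least 500 genes, at most 1% mitochondrial UMIs), no doublet removal, Leiden resolution 1.6, median-of-ratios size factors, edgeR 4.0.16 TMM factors, CPM over all UMIs, equal weight per nucleus, thinning to 1000 UMIs, a list minimum of 200 UMIs, no list minimum with 0.5 added, a 2-fold choice of genes, and 20 other random splits. Genotype groups, comparisons, gene lists, marker lists, the rule for named genes and these alternatives were fixed before the data were examined. Chosen after the data were seen were the median absolute log2 ratio as a summary of a comparison, its interval centred on its value, the count of lists outside the central 95%, the numbers of list members higher and lower, also against the median of all genes, and the score.

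The gene sums and the choice of genes were tested on simulated data made from the same 14424 genes. There, 95.6% of the ratio intervals held the true ratio. Genes other than those drawn as changed were left unchanged, so no shift of all genes was simulated. The intervals cover counting error only, so this share does not check the ratios between the real libraries. Of the genes drawn at 1.5-fold, 1.59% of 63 were chosen, of those at 2-fold 76.1% of 67, and of those at 4-fold 100% of 70, with 9 unchanged genes chosen. The signed median of 2-fold genes was 1.00 for a true value of 1. Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used. Gene sums of a 3′ assay show neither the sequence of Rbm20 nor splicing, so neither the genotypes nor splicing could be examined.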

Results

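Nuclei of adult mouse hearts were profiled in 4 libraries, 1 per genotype and each from 3 pooled hearts, so every value below rests on n = 1 library. WT held 9494 barcodes with 37180791 UMIs, Rbm20_het 9734 with 42375104, Rbm20_homo 11611 with 52370368, and the corrected library 15153 with 51422458. After filtering, 8681, 8871, 10443 and 13144 nuclei were analysed, with median depths of 2855, 3018, 3146 and 2365 UMIs. Ventricular cardiomyocyte-like nuclei numbered 2946, 2406, 2945 and 3083, with medians of 4847, 5693, 5894 and 4515 UMIs. Values in brackets are 95% intervals of counting error.

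The first question was whether the makeup of the nuclei differed between genotypes. Ventricular cardiomyocyte-like nuclei made up 33.9% of WT [32.9 to 34.9], 27.1% of Rbm20_het [26.2 to 28.1], 28.2% of Rbm20_homo [27.3 to 29.1] and 23.5% of the corrected library [22.7 to 24.2]. Fibroblast-like nuclei made up 22.1% of WT [21.2 to 23.0], 26.0% of Rbm20_het [25.1 to 26.9], 29.3% of Rbm20_homo [28.5 to 30.2] and 27.7% of the corrected library [27.0 to 28.5]. Endothelial-like nuclei were lowest in Rbm20_homo at 12.3% [11.7 to 12.95], against 14.7% in WT, 15.9% in Rbm20_het and 17.6% in the corrected library. Pericyte-like nuclei followed the same order, at 4.72% [4.32 to 5.15] in Rbm20_homo, 6.49% in WT, 8.35% in Rbm20_het and 8.74% in the corrected library. Among nuclei outside the cardiomyocyte class, fibroblast-like nuclei were 40.9% in Rbm20_homo against 33.4% in WT, and pericyte-like nuclei 6.58% against 9.82%. Macrophage-like nuclei were 4.40%, 3.66%, 4.35% and 5.90% in WT, Rbm20_het, Rbm20_homo and the corrected library. Endocardial-like nuclei were 2.95%, 2.41%, 3.90% and 2.31%, lymphatic endothelial-like nuclei 1.42%, 1.72%, 2.59% and 1.33%, and smooth muscle-like nuclei 0.887%, 1.17%, 1.39% and 1.24% in the same order. Smaller classes were T cell-like (0.311% in WT to 0.654% in the corrected library), B cell-like (0.345% in Rbm20_homo to 0.799% in the corrected library), Schwann-like (0.288% in WT to 0.507% in Rbm20_het) and mesothelial-like (0.2815% in the corrected library to 0.795% in Rbm20_homo). Cycling-like nuclei numbered 71, 33, 136 and 19, or 0.818%, 0.372%, 1.30% and 0.145%. Such shares also move with nuclei isolation and pooling, which 1 library per genotype leaves unmeasured.

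**Figure D1:**
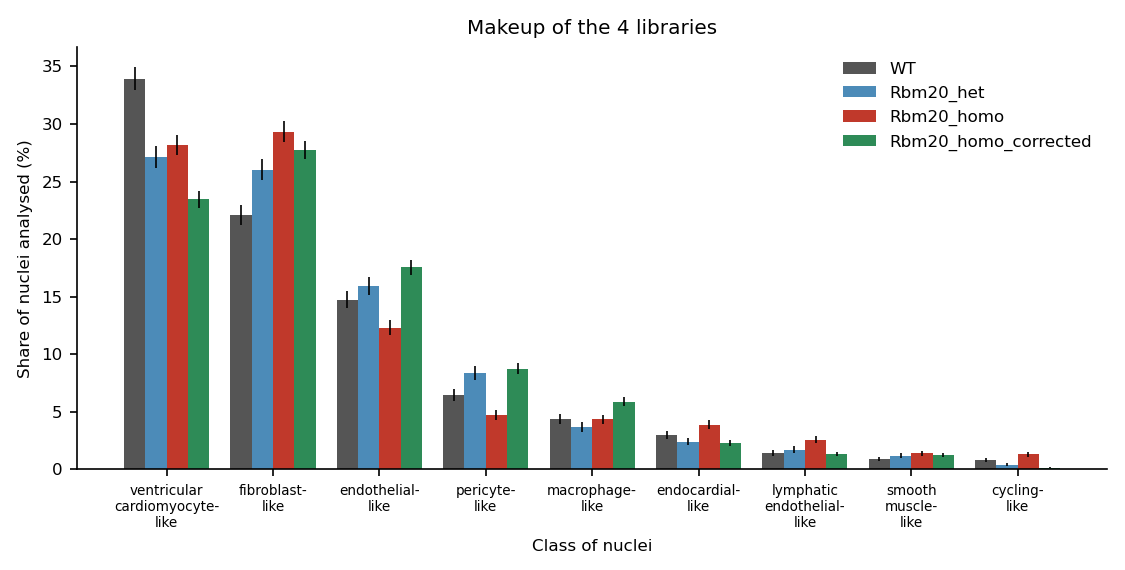
Share of nuclei analysed (%) in 9 classes for the 4 libraries, with exact 95% Clopper-Pearson intervals as bars. Ventricular cardiomyocyte-like nuclei range from 23.5% in the corrected library to 33.9% in WT.

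Rbm20 (ENSMUSG00000043639, chromosome 19, 53677306 to 53867080, GRCm38), the mutated gene and a regulator of splicing in heart muscle, was abundant in ventricular cardiomyocyte-like nuclei of every library. Its level was 4552 CPM in WT [4519 to 4585], 4571 in Rbm20_het, 3812 in Rbm20_homo [3784 to 3839] and 4703 in the corrected library. The log2 ratio of Rbm20_homo to WT was -0.26 [-0.27 to -0.24] by CPM, but -0.07 with median-of-ratios and -0.08 with TMM factors. Over 6865 genes with at least 500 UMIs the median log2 ratio of Rbm20_homo to WT was -0.20 by CPM and -0.01 and -0.02 with the other factors, so CPM ratios of this comparison are to be read against that shift. The median of the corrected library to Rbm20_homo, over 6727 genes, was 0.13, 0.01 and 0.02. Malat1, a nuclear noncoding RNA, took 24.1% of the cardiomyocyte-like UMIs in Rbm20_homo, against 14.4% in WT, 15.4% in Rbm20_het and 15.4% in the corrected library.

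Rbm20_homo was compared with WT for the effect of the homozygous mutation. In ventricular cardiomyocyte-like nuclei, the 12 genes ranked highest in Rbm20_homo were led by Nppa, which encodes atrial natriuretic peptide. Nppa (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079) stood at 9.81 CPM in WT, 32.4 in Rbm20_het, 932 in Rbm20_homo and 38.1 in the corrected library, 94.97-fold higher in Rbm20_homo than in WT [81.2 to 112], but its CPM was about as high in other classes of the same library (given below), so the source of these transcripts is open. Tpm2, a tropomyosin gene, was at 1.74, 10.7, 134 and 20.9 CPM in the same order, 77.3-fold [53.4 to 117], and Casq1, the calsequestrin of skeletal muscle, at 8.94, 40.8, 173 and 59.0 CPM, 19.4-fold [16.4 to 23.0]. Fkbp5, a co-chaperone induced by glucocorticoids, was at 14.5, 75.1, 236 and 27.6 CPM, 16.3-fold [14.3 to 18.6]. Gnao1, a G protein subunit, was at 27.6, 132, 352 and 105 CPM, 12.7-fold [11.6 to 14.0]. Syndig1 was at 2.79, 5.11, 78.6 and 8.73 CPM, Tent5b at 0.497, 1.29, 19.2 and 0.637, Map1a at 1.24, 4.59, 23.3 and 6.75, and the potassium channel gene Kcnj6 at 0.869, 0.775, 16.6 and 1.08. Lncbate10 (0.124, 1.03, 6.06 and 0.892 CPM), Paqr6 (0.186, 3.23, 7.18 and 0.319 CPM) and Tex50 (0.124, 0.323, 5.25 and 0.573 CPM) rested on 2 or 3 UMIs in WT, with folds of 48.8 [13.2 to 408], 38.5 [12.9 to 189] and 42.2 [11.4 to 354].

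The 12 lowest genes of this comparison were headed by Myh7b, a myosin heavy chain gene. Myh7b (ENSMUSG00000074652, chromosome 2, 155611212 to 155634307) stood at 356 CPM in WT, 1.29 in Rbm20_het, 0.306 in Rbm20_homo and 164 in the corrected library, 1165-fold lower in Rbm20_homo than in WT [535 to 3177]. Hopx, a homeodomain gene of the developing heart, was at 76.1, 11.6, 0.560 and 39.2 CPM in the same order, 136-fold lower [75.7 to 273]. Strit1, whose micropeptide raises the activity of the calcium pump of the sarcoplasmic reticulum, was at 6.52 CPM in WT, 0 in Rbm20_het and Rbm20_homo, and 1.40 in the corrected library, at least 42.7-fold lower in Rbm20_homo than in WT. Aqp4, a water channel gene, was at 7.58, 1.68, 0 and 1.47 CPM, at least 49.6-fold lower. Mylk4, a myosin light chain kinase gene, was at 481, 384, 27.7 and 283 CPM, 17.4-fold lower [15.9 to 19.0]. Lgi1 was at 16.2, 6.33, 0.153 and 11.1 CPM, Mme at 23.0, 5.43, 0.356 and 5.35, Pm20d1 at 39.7, 12.7, 1.38 and 13.9, Rp1 at 65.9, 11.1, 2.85 and 12.1, and P2rx6 at 10.7, 3.23, 0.356 and 2.93. The regulators of G protein signalling Rgs13 (11.2, 2.39, 0.102 and 1.72 CPM) and Rgs7 (114, 49.4, 7.18 and 43.2 CPM) were among them too. Within the cardiomyocyte class most nuclei of WT, Rbm20_het and the corrected library (2900, 2263 and 2764) shared a cluster that held 61 Rbm20_homo nuclei, while 2884 Rbm20_homo nuclei formed most of another, with 46, 143 and 319 of the others. The cluster of most WT nuclei had 9 enriched ventricular cardiomyocyte markers and that of most Rbm20_homo nuclei 3, the minimum for a name. Enrichment was measured against all other nuclei, those of the other cardiomyocyte-like cluster included. At Leiden resolution 1.6, the cardiomyocyte-like clusters other than that of most Rbm20_homo nuclei differed in makeup. The largest held 1413, 810 and 1424 nuclei of WT, Rbm20_het and the corrected library. The others held 305, 1243 and 898, then 1097, 164 and 385, then 108, 89 and 95 in that order.

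**Figure D2:**
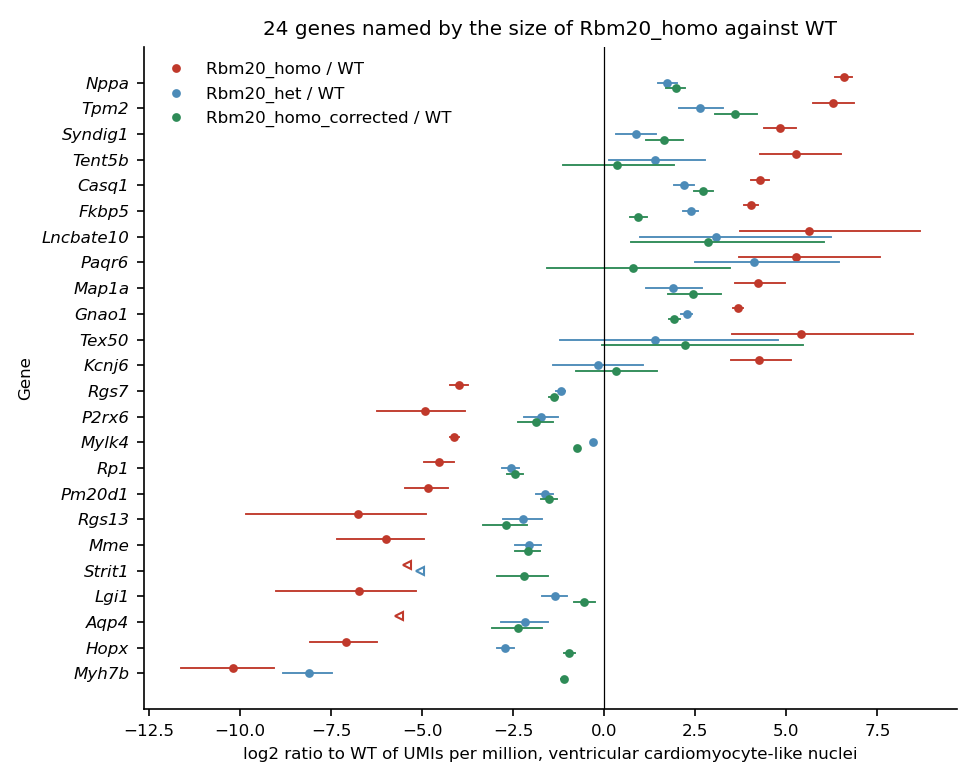
Log2 ratio to WT of the CPM in ventricular cardiomyocyte-like nuclei for the 24 genes named by the size of Rbm20_homo against WT, with 95% intervals of counting error as bars. Open triangles mark upper limits from a count of 0. Nppa stands at 6.57 and Myh7b at -10.19 in Rbm20_homo.

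Members of gene lists are counted as higher or lower against no change, and for some lists of this comparison also against the median of all genes, -0.20. By gene list, the stress and fetal genes had a median log2 ratio of 0.94 in Rbm20_homo against WT, above 100% of matched random lists, with 10 of 12 measured members higher. Nppb, the gene of B-type natriuretic peptide, was at 112 CPM against 12.5, Ccn2 at 50.1 against 6.64 and Acta1, skeletal actin, at 50.7 against 6.77. Fatty acid oxidation genes had a median of -0.95, below 100% of random lists, with 21 of 22 members lower and 19 below the median of all genes. Among them the uncoupling protein gene Ucp3 was at 12.99 CPM against 109 in WT, the fatty acid transporter gene Slc27a1 at 105 against 447, Ech1 at 35.1 against 106 and Acaa2 at 51.4 against 155. Ion channel and gap junction genes had a median of -0.49 (percentile 2.02, 10 of 16 lower, 9 below the median of all genes), where Kcnd2, a channel of the transient outward potassium current, was at 204 CPM against 1757, Kcnj3 at 145 against 671, Abcc9 at 81.0 against 333 and Kcnj2 at 10.9 against 35.3. Mitochondrial respiration and biogenesis genes had a median of -0.37 (percentile 6.14, 19 of 21 lower, 15 below the median of all genes), with Cox7a1 at 22.1 CPM against 47.2, Esrra at 120 against 239, Cox6a2 at 75.9 against 137 and Esrrb at 111 against 199. The median share of mitochondrial UMIs in cardiomyocyte-like nuclei was also lowest in Rbm20_homo, at 0.09% against 0.1685% in WT, 0.2068% in Rbm20_het and 0.179% in the corrected library. Less cytoplasmic RNA in that library would lower this share too, and whether it lowered these lists was not tested.

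Calcium handling genes split: the list median was 0.11 (percentile 98.3, 9 of 15 higher), while Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at 1241 CPM against 3380 in WT, its regulator Pln at 809 against 1499, Hrc at 51.5 against 129, and Casq2 at 499 against 271. Sarcomere and Z-disc genes had a median of -0.09 by CPM and 0.08 with TMM factors (percentile 88.4, 11 of 24 higher, but 14 above the median of all genes). In that list Tnni3, cardiac troponin I, was at 393 CPM against 961, Tcap at 292 against 684, Myl3 at 211 against 399 and Synpo2l at 99.5 against 44.6. Reported RBM20 splicing targets had a median of 0.07 (percentile 97.6, 9 of 17 higher), with the Z-disc genes Pdlim3 at 463 CPM against 53.6 and Pdlim5 at 1796 against 995, Enah at 847 against 253 and Rtn4 at 129 against 46.0. Splicing regulators had a median of 0.05 (percentile 95.1), with Rbfox1 at 244 CPM against 849, Celf2 at 2991 against 1982, Celf1 at 199 against 148 and Rbm24 at 772 against 596.

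Protein folding genes had a median of 0.08 (percentile 98.2, 9 of 17 higher), with the small heat shock genes Hspb1 at 52.2 CPM against 18.5 and Cryab at 133 against 83.2, Sqstm1 at 149 against 93.0 and Calr at 11.3 against 18.3. Glucose transport and glycolysis genes had a median of -0.12 by CPM and 0.06 with TMM factors (percentile 76.6), with Slc2a1 at 8.25 CPM against 3.35, Pfkp at 113 against 57.5, Hk2 at 217 against 422 and Ldhb at 160 against 270. Stress granule genes had a median of -0.26 (percentile 34.1), p53 targets 0.00 by CPM and 0.18 with TMM factors (percentile 81.7), interferon response genes 0.13 (percentile 88.5) and endothelial and angiogenic genes -0.27 (percentile 34.8). Members of these lists with the largest ratios were Ybx1 (35.7 CPM against 55.8), Cdkn1a (4.84 against 2.24), Ifit2 (7.54 against 2.55) and Vegfa (315 against 760). Immediate early genes, set in advance as a sign of tissue handling though not of that alone, had a median of 0.85 (percentile 99.9, 4 of 7 higher). Atf3 was at 6.16 CPM against 0.683, Btg2 at 35.3 against 11.7, Jun at 63.2 against 31.0 and Jund at 20.3 against 11.2. In endothelial-like nuclei the median of this list was 0.39 (percentile 98.1, 5 of 6 higher), but in fibroblast-like nuclei -0.13 (percentile 11.6, 2 of 7 higher). The cause was not tested. Circadian clock genes, a sign of the hour of collection, had a median of -0.82 (percentile 0.00, 10 of 14 lower, 8 below the median of all genes), with Dbp at 21.6 CPM against 137, Hlf at 25.9 against 76.2, Nr1d1 at 11.2 against 29.9 and Cry2 at 25.8 against 59.5. Cell cycle genes had a median of 0.86 over 5 members (percentile 99.2), but -1.18 at 1000 UMIs per nucleus, and Cenpf was at 1.27 CPM against 16.5.

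Lists of other cell types did not all go the same way in the cardiomyocyte-like sums of Rbm20_homo. The extracellular matrix and fibroblast activation list had a median of 2.05 (percentile 100, 18 of 19 higher), with Postn, periostin, at 19.2 CPM against 1.18, Cilp at 7.69 against 0.248 and Ltbp2 at 3.92 against 0.372. Postn had 0.128 UMIs per nucleus there and 1.56 in fibroblast-like nuclei of the same library, where it was at 506 CPM. Macrophage genes had a median of 0.51 (percentile 97.2, inside the central 95% of random lists), with Lyve1 at 2.496 CPM against 0.993 and Cd9 at 6.16 against 2.67. The sex-linked list had a median of -0.10 by CPM and 0.08 with TMM factors (percentile 67.2, 1 of 5 higher). It mixes Xist and Tsix with genes of the Y chromosome, so its median cannot check the sex of the pooled hearts. In all, 10 of the 20 lists lay outside the central 95% of random lists, and 6 did at 1000 UMIs per nucleus.

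**Figure D3:**
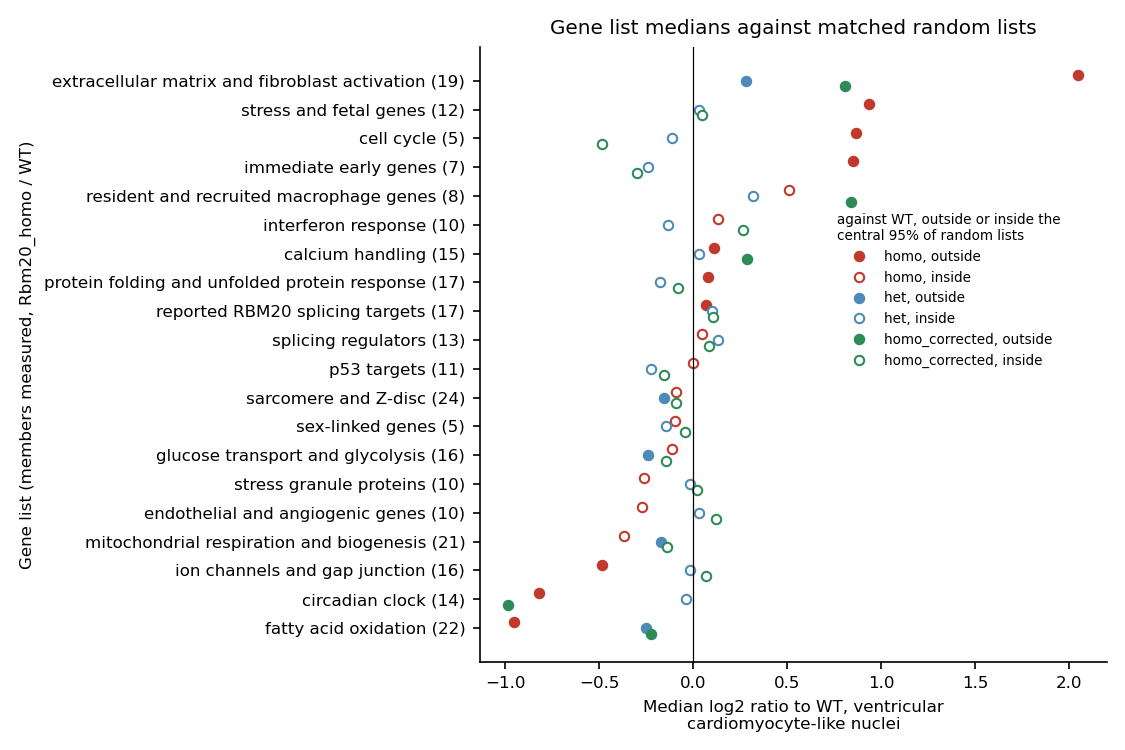
Median log2 ratio to WT of each gene list in ventricular cardiomyocyte-like nuclei of Rbm20_homo, Rbm20_het and the corrected library; filled points lie outside the central 95% of 10000 matched random lists. In Rbm20_homo the medians run from -0.95 for fatty acid oxidation to 2.05 for extracellular matrix genes; by TMM factors the sarcomere, glycolysis and sex-linked medians have the other sign.

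Rbm20_het was compared with WT for the effect of 1 mutant allele. Myh7b was 276-fold lower [178 to 452], Strit1 at least 33.6-fold lower, Hopx 6.58-fold lower [5.62 to 7.74], Rp1 5.93-fold lower and Pde11a, a phosphodiesterase gene, 5.12-fold lower. Plekhh1 was 5.51-fold, Vwc2 5.45-fold, Cntn3, a contactin gene, 5.07-fold and Gnao1 4.79-fold higher. Fatty acid oxidation genes had a median of -0.25 (percentile 0.00, 18 of 22 lower), mitochondrial genes -0.17 (percentile 0.87, 19 of 21 lower), glycolysis genes -0.24 (percentile 0.43), sarcomere genes -0.16 (percentile 0.88, 18 of 24 lower) and extracellular matrix genes 0.28 (percentile 99.7). Nppb was at 12.7 CPM against 12.5 in WT, and the stress and fetal list had a median of 0.03 (percentile 75.7). Ankrd1, a stress gene of that list, was at 1254 CPM against 479 in WT, 3059 in Rbm20_homo and 740 in the corrected library.

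The corrected library was compared with Rbm20_homo for the effect of the correction. Myh7b was 536-fold higher in the corrected library [246 to 1462], Hopx 69.9-fold [38.8 to 141], Lgi1 72.5-fold [24.4 to 355] on 3 UMIs in Rbm20_homo, Col13a1, a transmembrane collagen gene, 20.9-fold, the organic cation transporter gene Slc22a3 20.01-fold and Mylk4 10.2-fold. Nppa was 24.5-fold lower [22.5 to 26.6], and Tent5b, Ptgds (prostaglandin D synthase), Sema5a, Paqr6 and Kcnj6 were 30.1-fold, 16.9-fold, 14.0-fold, 22.6-fold and 15.3-fold lower. All 22 fatty acid oxidation genes were higher, with a median of 0.72 (percentile 100), and 15 of 16 ion channel genes were, with a median of 0.64 (percentile 99.98). Stress and fetal genes had a median of -1.34 (9 of 11 lower), extracellular matrix genes -1.30 (14 of 18 lower), cell cycle genes -1.10 and immediate early genes -0.85, each at or below percentile 0.14. This comparison and that of Rbm20_homo with WT share the Rbm20_homo library. The ABE features were counted in the corrected library only. An effect of the added sequences or of the treatment itself thus cannot be told apart from that of the correction, here or against WT.

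The corrected library was compared with WT for the distance left after correction. Clock genes stood out: Arntl, a core activator of the clock, was at 30.7 CPM against 2.92 in WT, 10.5-fold higher [7.79 to 14.5], while Ciart was 9.51-fold lower [7.16 to 12.9], Per3 4.94-fold and Dbp 4.08-fold lower, and the clock list had a median of -0.98 (percentile 0.00, 10 of 14 lower). Of the genes named for Rbm20_homo, Casq1 was 6.60-fold higher [5.53 to 7.92], and Rp1 5.45-fold and Rgs13 6.499-fold lower. Pnpla3, a lipid droplet lipase gene, was 11.4-fold higher [7.96 to 17.0], Slc41a3 5.87-fold, Cntn3 4.97-fold and the T-type calcium channel gene Cacna1h 5.17-fold higher, and the carboxylesterase gene Ces1d was 4.89-fold lower. Nppb was at 12.9 CPM against 12.5, and the stress and fetal median was 0.04 (percentile 81.7). Fatty acid oxidation genes had a median of -0.23 (percentile 0.14, 16 of 22 lower), calcium handling genes 0.29 (percentile 99.96), extracellular matrix genes 0.81 (percentile 100) and macrophage genes 0.84 (percentile 99.9). The macrophage list was set in advance as a sign of RNA of other cells in cardiomyocyte-like sums. How much of the matrix and macrophage lists is such RNA was not estimated, here or in the comparisons above.

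Across genes chosen for the difference between Rbm20_homo and WT and measured on nuclei held out, the signed median log2 ratio to WT was 1.31 in Rbm20_homo, 0.39 in Rbm20_het and 0.44 in the corrected library. The heterozygous and corrected values were 29.99% and 33.6% of the homozygous one. All 3 ratios share the WT library, so anything particular to that library adds to each, and 1 WT library gives no value for unchanged libraries. Genes higher in Rbm20_homo stood at 29.4% in Rbm20_het and 27.8% in the corrected library, and genes lower in Rbm20_homo at 31.1% and 36.9%. Over genes with at least 500 UMIs, the median absolute log2 ratio was 0.34 for Rbm20_homo against WT, 0.16 for Rbm20_het against WT, 0.26 for the corrected library against Rbm20_homo and 0.17 for the corrected library against WT, beside 0.07 between random parts of WT and 0.07 between those of Rbm20_homo. Scores of single cardiomyocyte-like nuclei had medians of -2.37 in WT, -1.56 in Rbm20_het, 0.06 in Rbm20_homo and -1.62 in the corrected library, with SDs of 0.465, 0.385, 0.445 and 0.492. Past the midpoint of the WT and Rbm20_homo medians lay 1.22% of 1472 WT nuclei, 13.8% of 2406 Rbm20_het nuclei, 99.6% of 1472 Rbm20_homo nuclei and 16.9% of 3077 corrected nuclei. The heterozygous and corrected shares depend on where this cut is set, since 29.05% of Rbm20_het and 25.2% of corrected nuclei lay within 0.25 of it, against 1.90% in WT and 0.883% in Rbm20_homo.

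**Figure D4:**
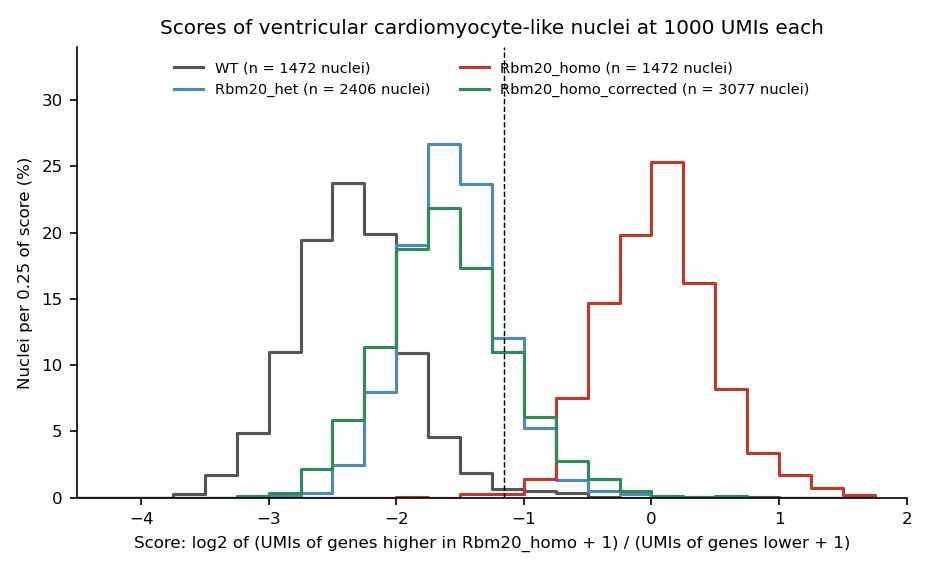
Distribution of the score per ventricular cardiomyocyte-like nucleus (% of nuclei per bin of 0.25) at 1000 UMIs per nucleus in the 4 libraries; the dashed line marks the midpoint at -1.15. Rbm20_het and corrected nuclei peak between WT and Rbm20_homo.

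In the other classes Rbm20_homo was again compared with WT. Fibroblast-like nuclei of Rbm20_homo had higher levels of many matrix genes: Postn was at 506 CPM against 17.6 in WT, 21.7 in Rbm20_het and 20.7 in the corrected library, 28.7-fold higher than in WT [23.2 to 35.8], Cilp was 32.5-fold and Ltbp2 32.0-fold higher. Thbs4, a thrombospondin gene, was at 29.4 CPM against 1 UMI in WT, 147-fold higher [26.1 to 5817]. The matrix list had a median of 1.55 in fibroblast-like nuclei (percentile 100, 21 of 24 higher). Ret and Gfra1, which encode a receptor and co-receptor for glial cell line-derived neurotrophic factor, were 10.9-fold and 9.86-fold lower, at 5.72 and 41.6 CPM against 62.6 and 410.4, beside 50.2 and 238 in the corrected library. Wnt11, Cxcl14, Blnk and Tll2 were 16.4-fold, 12.9-fold, 12.2-fold and 9.54-fold lower. Protein folding genes had a median of 0.39 (percentile 99.91, 16 of 17 higher). Other lists moved as well in these nuclei. Stress and fetal genes, a list that shares Ccn2 and Acta2 with the matrix list, had a median of 1.59 (percentile 100, 7 of 10 higher). Ion channel genes had -0.70 (9 of 10 lower), fatty acid oxidation genes -0.31 (19 of 21 lower) and sarcomere genes -0.26 (16 of 24 lower), each of these 3 at or below percentile 0.02. Of the 3065 fibroblast-like nuclei of Rbm20_homo, 2656 were in a cluster that held 42, 135 and 148 nuclei of WT, Rbm20_het and the corrected library.

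Endothelial-like nuclei of Rbm20_homo had Zbtb16, a transcription factor gene induced by glucocorticoids, at 1123 CPM against 120 in WT, 9.33-fold [8.22 to 10.6], Fkbp5 at 529 against 49.4, the cell cycle inhibitor gene Cdkn1a at 51.5 against 5.95 and Mgp at 531 against 95.6. Lgals4 was 8.05-fold, the clock genes Dbp and Nr1d1 5.87-fold and 4.46-fold, Coro6 3.49-fold, Robo2 3.54-fold and Akap5 5.15-fold lower. The endothelial and angiogenic list had a median of -0.04 in its own class (percentile 49.4), while stress and fetal genes had 1.58 (9 of 10 higher), extracellular matrix genes 1.12 (13 of 15 higher) and ion channel genes -0.52 (8 of 10 lower) there. Pericyte-like nuclei of Rbm20_homo had Zbtb16 12.9-fold, Fkbp5 5.03-fold, Man2a1 4.996-fold, Ccn2 6.26-fold and Smarca1 4.94-fold higher, and Lgals4 5.96-fold, Nr1d1 7.32-fold, Dbp 4.94-fold, Ttyh2 4.38-fold and Col25a1 3.51-fold lower. Their stress and fetal list had a median of 1.80 (7 of 8 higher), the matrix list 0.56 (11 of 14 higher) and the ion channel list -0.63 (5 of 7 lower). In macrophage-like nuclei Fkbp5 was 5.95-fold, Ccn2 12.8-fold, Mgp 5.39-fold and Vcam1 7.04-fold higher, and the macrophage list had a median of 0.62 (percentile 100, 12 of 13 higher). Other lists differed as much there: extracellular matrix genes had a median of 1.89 (11 of 11 higher), stress and fetal genes 1.5 (7 of 8 higher), sarcomere genes -0.61 (17 of 23 lower) and ion channel genes -1.32 (7 of 8 lower).

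Transcripts of cardiomyocyte genes were counted in every class. Nppa was named as higher in Rbm20_homo in all 4 other classes, with 1.69 UMIs per nucleus in fibroblast-like, 2.01 in endothelial-like, 1.26 in pericyte-like and 2.5 in macrophage-like nuclei, beside 6.21 in cardiomyocyte-like nuclei, at median depths of 2810, 1619, 1950, 2140 and 5894 UMIs. In WT the same classes had 0.0141, 0.0117, 0.0178, 0.0262 and 0.0536 per nucleus. By CPM, Nppa of Rbm20_homo was at 548, 1149.6, 625 and 993 in these 4 classes against 932 in cardiomyocyte-like nuclei, and Acta1 was at 57.7 in endothelial-like against 50.7 in cardiomyocyte-like nuclei. Ttn, the gene of the muscle protein titin, was at 1048, 2340, 1436 and 3336 CPM against 17583 in the same order of classes, so Nppa was not spread over the classes as Ttn was. Nppa and Acta1 were also among the 10 top genes of the unnamed cluster of low depth, with haemoglobin and mitochondrial genes. Free RNA can give such values, and its share was not estimated here, so how much of the Nppa in cardiomyocyte-like nuclei is their own is not known. Nppb in endothelial-like nuclei (57.3 CPM against 2.75) and Ankrd1 in macrophage-like nuclei (630 against 100.2) were higher too, and Myh7b was lower in pericyte-like (4.02 against 48.9) and macrophage-like nuclei (1.75 against 74.3). In macrophage-like nuclei Ttn was at 5855 CPM in WT, and at 2829 in Rbm20_het and 3215 in the corrected library. Beside that, Kcnd2, Kcnj3, Pdzrn4 and Hs3st5 were 12.1-fold, 10.2-fold, 13.9-fold and 10.5-fold lower in macrophage-like nuclei of Rbm20_homo than of WT, and Pfkfb1, on 3 UMIs in Rbm20_homo, 24.2-fold [7.89 to 120.8].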

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

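In this part the tests of the chromosome region of Myh7b, of Myh7b by the state of corrected nuclei and of editor RNA were set before their results were seen; the tests of the Myh7b level after correction, of Myh7b in Rbm20_het against corrected nuclei, of the clock genes, of the mixture of nuclei and of the spread of scores were chosen only afterwards, and Myh7b took the place of Nppa as a weighed pattern before any test of Nppa was run.

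ABE_C and ABE_N, 2 features added to the mouse genes and absent from the comparisons of the report, had 3550 and 4992 UMIs in the corrected library and 0 in each of the other 3. ABE commonly stands for adenine base editor, but the sources used here do not define the sequences counted. Of the 3083 ventricular cardiomyocyte-like nuclei of the corrected library, 39.5% [37.7 to 41.2] had at least 1 UMI of either feature, at a median depth of 4515 UMIs. In fibroblast-like, endothelial-like, pericyte-like and macrophage-like nuclei the share was 2.88%, 2.47%, 2.18% and 2.45%, at median depths of 2262, 1473.5, 1837 and 1782 UMIs. At 1000 UMIs per nucleus, with 6, 62, 290, 43 and 74 shallower nuclei left out, the shares were 18.1% in cardiomyocyte-like nuclei and 1.12%, 1.44%, 1.36% and 0.713% in the others. The levels were 359 CPM in cardiomyocyte-like nuclei and 14.9, 18.7, 12.6 and 22.4 CPM in the other 4 classes, where free RNA of cardiomyocytes was not separated from RNA of the nuclei themselves.

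Myh7b was nearly absent from cardiomyocyte-like nuclei of both mutant libraries, at 1.29 and 0.306 CPM against 356 in WT. A variant at the gene carried by the mutant line and left by the correction would keep Myh7b low, but the corrected library had 0.460 of the WT level. A change of the whole region would lower the neighbours too, but 20 genes within 500 kb had a median log2 ratio of -0.167 in Rbm20_homo against WT, with the lowest, Pigu, at -0.52. A loss tied to the Rbm20_homo-like state of a nucleus is argued against for Rbm20_het by library levels already seen. These were 1.29 CPM against 164 in the corrected library, with most nuclei of both not past the midpoint. A test on those nuclei alone could hardly come out otherwise, so it adds little. It gave 1.21 CPM in Rbm20_het against 178, a ratio of 0.0068 [0.0039 to 0.0111], at similar median scores of -1.62 and -1.71. For Rbm20_homo, with 99.6% of nuclei past the midpoint, a loss tied to that state cannot be told apart from an even loss. Corrected nuclei past the midpoint had 0.517 of the level of the others [0.451 to 0.592], between the bounds set for either. An effect of the Rbm20 genotype on Myh7b was not tested.

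Clock genes of the corrected library differed from WT, as Arntl at 30.7 CPM against 2.92 and Ciart at 3.38 against 32.1 in cardiomyocyte-like nuclei show. A change in cardiomyocytes alone is argued against: over the 10 clock genes at least 0.5 in log2 from WT in cardiomyocyte-like nuclei and with at least 50 UMIs in each of 3 classes, the median absolute log2 ratio was 0.942 in fibroblast-like and 1.097 in cardiomyocyte-like nuclei, a ratio of 0.859. A different hour of tissue collection stays open for the corrected library, since the share of these genes with the same sign in cardiomyocyte-like, fibroblast-like and endothelial-like nuclei was 1.0 (10 of 10), though the labels used here give no hour. The UMI minimum left out Ciart and Per3, and the cut of 0.5 left out Hlf and Nr1d1. Hlf was lower than WT in all 3 classes. Nr1d1 was at 0.17 [-0.02 to 0.35] in cardiomyocyte-like, -1.04 in fibroblast-like and -0.22 in endothelial-like nuclei. In Rbm20_homo against WT the list medians were -0.82 in cardiomyocyte-like, -0.58 in endothelial-like and -0.44 in pericyte-like nuclei, but 0.14 in fibroblast-like and 0.06 in macrophage-like nuclei. Dbp (-2.67, -2.55, -2.30, -0.77 and -1.65 in that order) and Nr1d1 were lower in all 5 classes, while Ciart was at -1.02 in cardiomyocyte-like and 1.85 in fibroblast-like nuclei. The test above was not run for that library, where the cause stays open. An effect of genotype or editing on the clock of the whole heart was not tested and may look the same.

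Corrected cardiomyocyte-like nuclei lay between WT and Rbm20_homo, with a median score of -1.62 against -2.37 and 0.06. Nuclei past the midpoint alone do not make up this difference. Corrected nuclei not past it had a median score of -1.71, against -2.37 in such WT nuclei. RNA of other cells or a shift of the whole library could move these too. Whether nuclei left in the Rbm20_homo-like state account for the whole was thus not settled. The 5th percentile of Rbm20_homo scores was reached by 2.99% of corrected nuclei. That was 1.257 times [0.856 to 1.847] the 2.38% of WT nuclei moved by the difference of medians. But the ratio depends on its reference. The score bin from -0.5 held 1.43% of corrected and 0.54% of Rbm20_het nuclei, whose median score was similar. Among higher bins only that from 0.25 went the other way, at 0.0325% and 0.0416%. The test thus cannot decide whether a small share of nuclei left in the Rbm20_homo-like state is present. The percentile test, and later its interval, replaced a first one by the midpoint, passed by 13.8 times the WT share of nuclei. The reason was that WT nuclei moved by the difference of medians gave 13.6% there, near the 16.9% seen. The SD of the corrected scores was 1.058 times that of WT, near what an even move of all nuclei would give. But Rbm20_het, at a similar median score of -1.56, had an SD of 0.385 against 0.492 in the corrected library. The SD test thus depends on its reference and cannot decide on an even move, which stays open. A link to editor RNA stays open too. Of 1217 nuclei with an ABE UMI 8.71% were past the midpoint, and of 1860 without 22.3%. The Mantel-Haenszel ratio over depth quintiles was 0.388 [0.316 to 0.476]. Its interval takes nuclei as units and leaves out differences between the pooled hearts. Median scores were -1.76 in nuclei with an ABE UMI and -1.52 in those without. Incomplete correction may be part of the pattern but was not measured. Effects of RNA of other cells, of pooling or of the library were not separated from it, with 1 library per genotype.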

How the results depend on the processing

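The alternatives below were planned, except that the median absolute log2 ratio, its interval centred on its value, and the count of lists were chosen as summaries only after the results were seen. Of 311 alternative values of the main results over 14 settings, 218 stayed within the counting interval (or within 1.5 times, for counts) and 93 moved out of it. Over all 2837 alternative values, named genes and lists included, 2417 stayed, 411 moved and 9 changed sign; of 2625 signed values, 66 had the other sign, counting those whose interval includes 0. Ventricular and atrial cardiomyocyte-like nuclei could not be pooled, because no atrial-like cluster was found. No paired analysis was possible because each genotype has 1 library. Unless said otherwise, the cause was not tested.

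With all deposited barcodes, so with neither the filter nor doublet removal, shares in WT, Rbm20_het, Rbm20_homo and the corrected library were 32.6%, 26.1%, 27.0% and 21.8% cardiomyocyte-like, 20.2%, 23.8%, 26.3% and 24.2% fibroblast-like, 13.3%, 14.3%, 10.8% and 15.02% endothelial-like and 5.96%, 7.69%, 4.25% and 7.66% pericyte-like. Median absolute log2 ratios in cardiomyocyte-like nuclei were then 0.330 (Rbm20_homo against WT), 0.156 (Rbm20_het against WT), 0.259 (corrected against Rbm20_homo) and 0.166 (corrected against WT), and 0.220 in macrophage-like nuclei. The macrophage list in macrophage-like nuclei had a median of 0.43. As both choices changed at once, these moves are not put down to the filter. With the stricter filter Rbm20_het had 28.2% cardiomyocyte-like and 15.1% endothelial-like nuclei.

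Without doublet removal the shares were 31.3%, 25.0%, 25.5% and 20.6% cardiomyocyte-like, 20.4%, 23.98%, 26.7% and 24.5% fibroblast-like and 13.8%, 14.7%, 11.2% and 15.5% endothelial-like in the same order. Pericyte-like shares were 7.73%, 4.29% and 7.74% in Rbm20_het, Rbm20_homo and the corrected library, and macrophage-like shares 3.92%, 3.96% and 5.28% in WT, Rbm20_homo and the corrected library. At resolution 1.6 the macrophage-like shares were 3.76% in Rbm20_homo and 5.42% in the corrected library.

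With median-of-ratios factors the log2 ratio of Rbm20 was -0.070 (Rbm20_homo against WT), 0.066 (Rbm20_het against WT), 0.18 (corrected against Rbm20_homo) and 0.11 (corrected against WT), and with TMM factors -0.082, 0.069, 0.20 and 0.11. It was -0.010 for Rbm20_het against WT with equal weight per nucleus, and 0.32 for the corrected library against Rbm20_homo at 1000 UMIs. The median absolute log2 ratios of the 4 comparisons were 0.279, 0.156, 0.235 and 0.165 with median-of-ratios and 0.280, 0.157, 0.237 and 0.165 with TMM factors. These factors remove the shift of all genes, which by construction also moves each ratio. Ddx3y and Uty, lower in Rbm20_homo than in WT by CPM, had 0.017 and 0.087 with median-of-ratios and 0.0051 and 0.075 with TMM factors.

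With equal weight per nucleus the median absolute log2 ratio was 0.179 for the corrected library against WT and 0.204 in endothelial-like nuclei. At 1000 UMIs per nucleus it was 0.365, 0.207, 0.290 and 0.208 for the 4 comparisons in cardiomyocyte-like nuclei, and 0.232, 0.209, 0.258 and 0.224 in fibroblast-like, endothelial-like, pericyte-like and macrophage-like nuclei. Thinning leaves fewer counts, which limits genes of low level. There, 6 lists instead of 10 lay outside the central 95%, the matrix list in fibroblast-like nuclei had a median of 1.07, and in Rbm20_homo against WT the medians of the RBM20 target list (-0.069) and the cell cycle list (-1.18), and the ratios of Mrc1 (-0.22), Usp18 (-0.74) and Eif2s3y (-0.0008), had the other sign.

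The signed median log2 ratio to WT in Rbm20_homo was 1.27 with all deposited barcodes, 1.28 without doublet removal, 1.28 at resolution 1.6, 1.33 with median-of-ratios, 1.34 with TMM factors, 1.198 with equal weight, 1.38 at 1000 UMIs, 1.90 with genes chosen at 2-fold and 1.26 in the lowest of 20 splits. In Rbm20_het it was 0.37 without doublet removal, 0.37 at resolution 1.6, 0.36 with equal weight, 0.41 at 1000 UMIs, 0.57 at 2-fold and 0.37 in the lowest split. In the corrected library it was 0.41 with all deposited barcodes, 0.48 at 1000 UMIs, 0.61 at 2-fold and 0.41 in the lowest split. As a share of Rbm20_homo, the settings other than the 20 splits gave 28.9% to 30.1% in Rbm20_het and 32.0% to 35.6% in the corrected library.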

Other observations

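The test of shared barcodes was chosen only after the result was seen, as were Fkbp5 and Zbtb16 in fibroblast-like nuclei, Zbtb16 in cardiomyocyte-like and macrophage-like nuclei, and the clock genes named here. Fkbp5 and Zbtb16, both induced by glucocorticoids, were higher in Rbm20_homo than in WT in all 5 classes. Fkbp5 stood at 14.5, 75.1, 236 and 27.6 CPM in cardiomyocyte-like nuclei of WT, Rbm20_het, Rbm20_homo and the corrected library, at 300.05, 607, 939.7 and 517 in fibroblast-like nuclei and at 192, 479, 1139.8 and 309 in macrophage-like nuclei. Zbtb16 stood at 341, 1058, 1128 and 758 CPM in cardiomyocyte-like nuclei, at 451, 843, 1320.3 and 907 in fibroblast-like nuclei, at 120, 694, 1123 and 421 in endothelial-like nuclei, at 73.4, 343, 948.6 and 286 in pericyte-like nuclei and at 182, 374, 741 and 342 in macrophage-like nuclei.

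Clock genes of the corrected library differed from WT outside muscle as well. Arntl was at 85.2 CPM in fibroblast-like nuclei of the corrected library against 10.6 in WT, and at 65.1 against 6.41 in endothelial-like nuclei. Per2 was at 19.5 against 45.9 and at 21.0 against 72.3 in the same classes, and Dbp at 28.4 against 124 and at 34.1 against 130.4.

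Barcodes shared between libraries, as index hopping or a swap of droplets would leave, were tested as a source of corrected nuclei that look like Rbm20_homo. Of the 520 corrected nuclei past the midpoint, 3 had a barcode also in the Rbm20_homo library, or 0.577% [0.119 to 1.68], far under the share that this source would need. Of the 2557 others 6 did, or 0.235%. A first form of this test, the ratio of those shares (2.46), was dropped after it was seen because it rested on 3 and 6 nuclei.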
